A study of Mus musculus with 60 samples.

How the data were processed

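Liver total RNA of 60 mice of strain CC042/GeniUnc was sequenced after 20, 40 or 60 weeks on a high-fat and high-sucrose (HF/HS) diet or on an ingredient-matched control diet, with 5 animals in each of the 12 groups of sex, diet and duration. Groups and animal numbers were taken from the labels. The numbers were different in all libraries, and what they stand for is not given in the sources used here. Per the labels' protocols, livers were flash frozen and RNA was extracted with miRNeasy kits, depleted of ribosomal RNA and made into stranded libraries. The deposited table held whole-number counts per gene symbol and library, per the labels 1 column for each animal. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation and the use of strand in counting are not given in the sources used here.

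The table had 24982 gene entries, of which 4778 had no count in any library. In 26 lines the symbol had been spoiled into a calendar date. These held 0.201% of the counts, and they stayed in the library totals and tests but were never named. Mitochondrially encoded genes numbered 0 in the table. Within groups, counts of any pair of libraries differed by more than sampling noise (chi-square per degree of freedom at least 3.34). Pearson's r over genes was 0.955 to 0.995. Every library counted as 1 replicate, but independence of adjoining animal numbers was not tested. Gene positions are those of GENCODE M21 for mm10, matched by symbol.

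All 60 libraries entered a single edgeR quasi-likelihood model of the 12 group means without covariates, with trimmed mean of M values (TMM) scaling and filterByExpr at its defaults (minimum count 10, minimum total 15), which left 14180 genes. Contrasts gave the diet effect in each sex and duration, its difference between the sexes (female minus male), its change from 20 to 60 weeks, the change with age on the control diet and the sex difference on each diet. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no minimum fold. Standard errors were the log2 fold change over the square root of its F statistic. Against a group with 0 counts, a fold was bounded with 3 counts over the group, and with 1 to 3 counts the ratio was given with an exact 95% interval. Such bounds and intervals cover counting error only.

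Of the 39 gene lists of pathways and cell types, 37 had at least 5 tested members and were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation and fry, which tests each list on its own, were alternatives. The lists covered lipid, bile acid, glucose, one-carbon and xenobiotic metabolism, matrix, inflammation, proliferation, stress and sex-biased genes, and markers of liver, immune and neighbouring tissue cells. The erythroid list and the gut and gallbladder list were counted only. The genes named were those of a fixed rule. It took (a) the 5 highest and the 5 lowest log2 fold changes of each comparison among called genes with a mean of at least 1 CPM, symbols that are not provisional and, for diet and age comparisons, CPM ranges of the groups that did not overlap. It also took (b) up to 4 called members of each list in a diet comparison, or up to 2 in another, with the largest absolute change, and (c) a panel of 22 genes in the diet comparisons whatever they showed. Examples were drawn from these, so not every one is named, and genes outside the rule are named as such. The groups, tests, lists, naming rule and all but 2 of the alternatives were fixed before the data were examined.

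The alternatives for each count were relative log expression (RLE) size factors, the DESeq2 Wald test, limma voom with sample quality weights, no filter on low counts, removal of 137 small non-coding RNA genes (31 of them tested) before scaling, the range of the animal number as a covariate, and a fit of the comparison's own libraries only, beside leaving out each library in turn. After the data had been seen, a further 2 were added: leaving out 4 libraries that stood apart from their groups (male control 20 weeks animal 373, female control 20 weeks animal 383, female control 60 weeks animal 31 and male HF/HS 60 weeks animal 91), and the first principal component of the clock list as a covariate. Other splits of the same libraries were refitted with those libraries alone. Of these, 60 splits were drawn for each diet and age comparison, 40 for each difference or change of the diet effect and 24 for each sex comparison, the real split included. A library's list score was the mean log2 CPM of the list (prior count 2), and groups of 5 were searched for outlying libraries with Dixon's ratio.

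The model was tested on simulated counts for 14180 genes with 200 changed. For the diet effect in males at 20 weeks, 169 genes were called, 8 of them false, and 65.7%, 82.1% and 93.9% of genes changed by 1.5-, 2- and 4-fold were recovered. For the difference between sexes at 20 weeks, 150 were called, 8 of them false, and recovery was 47.8%, 73.1% and 92.4%. For the change from 20 to 60 weeks in males, 156 were called, 14 of them false, and recovery was 52.2%, 73.1% and 87.9%. In an unchanged comparison, of control males at 60 and 20 weeks, edgeR called 0 genes. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.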

Results

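Total RNA was sequenced from the livers of 60 CC042/GeniUnc mice, a Collaborative Cross inbred strain. Each sex was fed either a diet rich in fat and sucrose (HF/HS) or an ingredient-matched control diet low in fat and reduced in sucrose, for 20, 40 or 60 weeks, which gave 12 groups of 5 animals. The deposited table gave 1 count per gene and library for 24982 gene entries. Library totals ran from 10923963 to 20942463 counts. Of the 24982 entries, 14180 had enough counts to be tested. Values below are mean ± SD of counts scaled by library size (CPM), or log2 fold changes ± standard error, with 5 animals per group unless stated. Families of near-identical genes (Cyp3a, Cyp4a, Cyp2a, Cyp2c, Sult2a, Sult3a, Mup, Gsta, Gstm, Gstp, Saa, Orm, Serpina1, Slc22a26 and Slc22a27, H2 and the pancreatic enzymes) can share reads, so values of single members are uncertain. Overlapping and antisense genes such as Xist and H19 are uncertain in the same way, since the use of strand in counting is not given in the sources used here.

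Genes of the sex chromosomes separated the libraries by their labelled sex. Xist, the RNA that silences an X chromosome, was at 3956 ± 596 CPM in the 30 female libraries (lowest 3140) and 0.387 ± 0.326 CPM in the 30 male libraries (highest 1.30). Of the Y-linked genes, Uty was at 52.2 ± 4.75 CPM in males and at most 0.0718 CPM in any female library, and Kdm5d was at 36.6 ± 5.11 CPM in males and at most 0.215 CPM in females. Ddx3y ranged from 16.1 to 171 CPM and Eif2s3y from 6.80 to 62.0 CPM among male libraries. Over all tested genes, the first principal component held 33.0% of the variance and the second 24.5%.

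**Figure D1:**
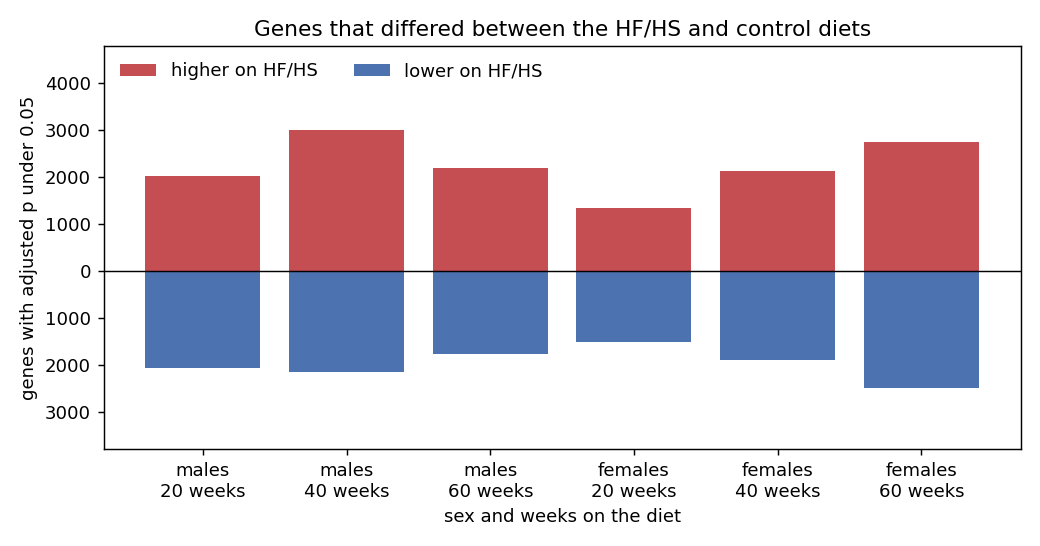
Bars give the number of genes (y axis) with edgeR adjusted p under 0.05 that were higher (above 0) or lower (below 0) on the HF/HS diet in each sex and duration (x axis), 5 animals per group. The number of higher genes ran from 1351 in females at 20 weeks to 3006 in males at 40 weeks.

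In males at 20 weeks, Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.123 ± 0.0732 to 32.8 ± 4.29 CPM, a log2 fold change of 8.0 ± 0.81. Mmp12, the macrophage elastase, rose by 5.90 ± 0.64, and Mogat1, which makes diacylglycerol, by 5.05 ± 0.74. Muc13, an epithelial mucin, and Sprr1a, a cornified envelope protein, had 0 counts in all 5 controls and were at least 144-fold and at least 127-fold higher, against a floor of 3 counts over the group. Decreases included Trat1 (-6.98 ± 1.06), Dnah17 (-3.95 ± 0.58), Adgrf1 (-3.45 ± 0.47), Gucy2c (-3.22 ± 0.65) and Acpp (-2.83 ± 0.46). The highest adjusted p of these 10 genes was 0.000183 (edgeR, Benjamini-Hochberg). In total, 2034 genes rose and 2062 fell, 863 and 200 of them by at least 2-fold, and a fit of these 10 libraries alone called 1889 in place of 4096. Gucy2c was at -2.10 without animal 373.

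Among metabolic lists in males at 20 weeks, genes of cholesterol synthesis and uptake moved down: 0 of 23 rose and 17 fell (0 and 17 adjusted over the list alone, camera adjusted p = 1.32e-09, adjusted p = 0.204 with an estimated correlation). Squalene epoxidase and the next largest change were Sqle (-2.48 ± 0.48) and Idi1 (-1.52 ± 0.28). Lipid droplet and fatty acid uptake genes moved up: 12 of 19 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.31e-08, adjusted p = 0.115 with an estimated correlation), led after Mogat1 by the droplet protein Cidec (4.09 ± 0.69) and with the fatty acid transporter Cd36 (2.05 ± 0.27). 9 of 28 fatty acid oxidation genes rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000335, adjusted p = 0.553 with an estimated correlation), with Cyp4a10 (2.39 ± 0.59) first, and with the hepatokine Fgf21 (1.59 ± 0.36). 4 of 19 fatty acid synthesis genes rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.105, adjusted p = 0.767 with an estimated correlation), led by Scd2 (1.52 ± 0.39). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.44 ± 0.57 (adjusted p = 0.0498). Acute phase genes moved down: 0 of 21 rose and 10 fell (0 and 13 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.577 with an estimated correlation), led by Orm1 (-2.92 ± 1.01). Only control animals 371 (mean log2 CPM of the list 9.13) and 373 (9.69) lay above the HF/HS animals (7.65 to 8.22), and 181 (6.96) and 182 (6.86) lay below them. 0 of 30 ribosomal proteins rose and 29 fell (0 and 30 adjusted over the list alone, camera adjusted p = 8.75e-15, adjusted p = 0.138 with an estimated correlation). The panel genes Scd1 (0.42 ± 0.17), Fasn (0.79 ± 0.37), Cyp4a14 (0.53 ± 0.75), Cyp4a12a (0.23 ± 0.25), Hsd3b5 (-0.71 ± 0.54) and Mup20 (-0.68 ± 0.30) did not pass the test (lowest adjusted p = 0.0618). Cyp7a1 did not pass without animal 181, 371, 372, 373, 261, 271, 411 or 413 (1.43, 1.26, 1.5, 1.15, 1.46, 1.4, 1.57 and 1.11). Orm1 did not pass without animal 373 or 271 (-1.53 and -2.72). Scd1 passed without animal 181, 373 or 261 (0.51, 0.49 and 0.50), as did Fasn without animal 181 (1.33, adjusted p = 0.00677), as did Mup20 without animal 373 or 261 (-0.91 and -0.82).

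26 of 32 extracellular matrix and fibrosis genes in males at 20 weeks rose and 1 fell (26 and 1 adjusted over the list alone, camera adjusted p = 5.58e-15, adjusted p = 0.138 with an estimated correlation), with Mmp12 first, Timp1 (3.54 ± 0.68), an inhibitor of matrix proteases, and collagen Col1a1 (3.30 ± 0.45). 9 of 14 lipid-associated macrophage markers rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 2.22e-10, adjusted p = 0.102 with an estimated correlation), including Trem2 (2.92 ± 0.48), a lipid receptor of macrophages. 9 of 12 dendritic cell markers rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.01e-10, adjusted p = 0.0597 with an estimated correlation), led by H2-Eb1 (2.33 ± 0.27). 15 of 20 interferon response genes rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 2.73e-08, adjusted p = 0.204 with an estimated correlation). 19 of 25 cell cycle genes rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 1.4e-10, adjusted p = 0.138 with an estimated correlation), with the proliferation marker Mki67 (2.96 ± 0.52). The checkpoint kinase Bub1, first of that list, had 2 counts over the controls and was higher by a ratio of 36.6 with an exact 95% counting interval of 9.81 to 307. 9 of 15 p53 and senescence genes rose and 0 fell (9 and 1 adjusted over the list alone, camera adjusted p = 2.98e-06, adjusted p = 0.0938 with an estimated correlation), led by Phlda3 (2.08 ± 0.35) and Gdf15 (2.03 ± 0.39). Gpc3, an oncofetal proteoglycan, rose by 1.0 ± 0.32 (adjusted p = 0.0144), and Spp1 (0.54 ± 0.27), Afp (0.28 ± 0.26) and Cdkn1a (0.80 ± 0.46) did not pass the test (lowest adjusted p = 0.124). 1 of 10 skeletal and smooth muscle genes rose and 6 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.502, adjusted p = 0.881 with an estimated correlation), and the list's mean log2 CPM was highest in control animals 372 (3.63) and 373 (3.20). Gpc3 did not pass without animal 371 (0.75, adjusted p = 0.0713).

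In males at 40 weeks, Ubd, a ubiquitin-like modifier, rose from 0.847 ± 0.252 to 11.2 ± 7.32 CPM, a log2 fold change of 3.70 ± 0.54. The other large increases were in Lrtm2 (3.67 ± 0.51), Ptgfr (3.64 ± 0.64), Gipc2 (3.52 ± 0.68) and Muc13 (3.49 ± 0.67). Moxd1, a male-biased monooxygenase, fell from 374 ± 150 to 28.5 ± 5.62 CPM, a change of -3.71 ± 0.94, beside Pcdh20 (-3.58 ± 0.77), Rnase2a (-3.45 ± 0.84), Slc35f1 (-3.43 ± 0.69) and Dnah17 (-2.92 ± 0.48). Among these 10 genes the highest adjusted p was 0.00172 (edgeR). In total 3006 genes rose and 2156 fell, so that 58.2% of the calls were higher, against 48.1% when small non-coding RNA genes were removed before scaling.

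29 of 32 extracellular matrix and fibrosis genes in males at 40 weeks rose and 0 fell (30 and 0 adjusted over the list alone, camera adjusted p = 1.4e-19, adjusted p = 0.0842 with an estimated correlation), led by Col1a1 (2.78 ± 0.41) and Mmp12 (2.75 ± 0.47), with Timp1 (2.25 ± 0.50). 13 of 13 general macrophage markers rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.09e-08, adjusted p = 0.227 with an estimated correlation), led by the protease Ctss (1.68 ± 0.31). 12 of 14 lipid-associated macrophage markers rose and 0 fell (12 and 1 adjusted over the list alone, camera adjusted p = 6.89e-09, adjusted p = 0.0842 with an estimated correlation), with Gpnmb (2.79 ± 0.47) and Trem2 (2.38 ± 0.44) and osteopontin Spp1 (1.88 ± 0.26). 10 of 13 bile duct cell markers rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 5.01e-07, adjusted p = 0.0842 with an estimated correlation), led by the tight junction gene Cldn4 (3.32 ± 0.67) and the chloride channel Cftr (3.24 ± 0.49). 7 of 9 T and natural killer cell markers rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0059, adjusted p = 0.251 with an estimated correlation), led by Il2rb (2.46 ± 0.50). 18 of 22 chemokines and cytokines rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 1.23e-07, adjusted p = 0.161 with an estimated correlation), led by Ccl22 (2.91 ± 0.65). 14 of 20 fetal liver and liver tumour genes rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.0842 with an estimated correlation), led by the imprinted RNA H19 (3.16 ± 0.63). 7 of 13 stellate cell markers rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00328, adjusted p = 0.241 with an estimated correlation), led by Dpt (1.33 ± 0.32). Of the hepatocyte markers, 0 of 15 rose and 10 fell (0 and 11 adjusted over the list alone, camera adjusted p = 1.22e-07, adjusted p = 0.0842 with an estimated correlation), led by the histidine ammonia-lyase Hal (-1.01 ± 0.12). The panel gene Mki67 (1.82 ± 0.47, adjusted p = 0.00187) rose, and Afp (0.04 ± 0.25), Gpc3 (0.62 ± 0.31), Cdkn1a (-0.28 ± 0.48) and Gdf15 (0.24 ± 0.37) did not pass the test (lowest adjusted p = 0.118).

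Male-biased liver genes moved down in males at 40 weeks: 0 of 23 rose and 14 fell (0 and 16 adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.251 with an estimated correlation), led after Moxd1 by the steroid dehydrogenase Hsd3b5 (-2.09 ± 0.56). Female-biased liver genes moved up: 12 of 27 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.000965, adjusted p = 0.396 with an estimated correlation), led by the peroxisomal transporter Abcd2 (2.59 ± 0.39). 10 of 19 lipid droplet and fatty acid uptake genes rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.00695, adjusted p = 0.396 with an estimated correlation), led by Cidec (3.20 ± 0.56) and with Cd36 (1.37 ± 0.27). 4 of 23 bile acid synthesis and transport genes rose and 8 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.402 with an estimated correlation), led by the exporter Abcc3 (1.58 ± 0.30) and with Cyp7a1 (1.56 ± 0.57, adjusted p = 0.0268). 8 of 13 immediate early genes rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00547, adjusted p = 0.296 with an estimated correlation), led by Fosb (2.41 ± 0.76). 0 of 20 glucose metabolism genes rose and 7 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.00251, adjusted p = 0.251 with an estimated correlation), led by the glucose-6-phosphatase G6pc (-1.27 ± 0.32). Fgf21 rose by 0.94 ± 0.32, and Sqle (0.01 ± 0.45), Scd1 (0.08 ± 0.17), Fasn (0.36 ± 0.37), Cyp4a14 (0.46 ± 0.62), Cyp4a12a (-0.12 ± 0.25) and Mup20 (-0.46 ± 0.30) did not pass the test (lowest adjusted p = 0.232). Cyp7a1 did not pass without animal 492, 493 or 503 (1.36, 1.48 and 1.48). Fgf21 did not pass without animal 493 or 522 (0.81 and 0.71).

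In males at 60 weeks, Ubd rose from 0.600 ± 0.440 to 6.60 ± 3.63 CPM (3.41 ± 0.56). The fractalkine receptor Cx3cr1 rose by 2.47 ± 0.36. The other large increases were in Elfn1 (3.19 ± 0.52), Rims2 (3.18 ± 0.51) and Itga2 (2.49 ± 0.52). Decreases included Pcdh20 (-4.08 ± 0.79), Dnah17 (-3.19 ± 0.52), Lrtm1 (-2.75 ± 0.44), Tiam1 (-2.46 ± 0.30) and Tiam2 (-2.25 ± 0.55). The highest adjusted p of these 10 genes was 0.00217 (edgeR). In total 2197 genes rose and 1777 fell, and a fit of these 10 libraries alone called 2203 in place of 3974. The HF/HS library of animal 91 stood apart from its group, and without it 4904 genes were called.

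26 of 32 extracellular matrix and fibrosis genes in males at 60 weeks rose and 1 fell (27 and 1 adjusted over the list alone, camera adjusted p = 7.77e-15, adjusted p = 0.17 with an estimated correlation), led by Timp1 (3.08 ± 0.55) and Col1a1 (2.26 ± 0.40). 11 of 14 lipid-associated macrophage markers rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.34e-08, adjusted p = 0.127 with an estimated correlation), with Trem2 (1.29 ± 0.41), Gpnmb (1.17 ± 0.44) and Spp1 (1.43 ± 0.26). 11 of 13 bile duct cell markers rose and 0 fell (12 and 1 adjusted over the list alone, camera adjusted p = 2.71e-08, adjusted p = 0.0774 with an estimated correlation), led by Cldn4 (3.20 ± 0.64). 3 of 12 sinusoidal endothelial cell markers rose and 0 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.596, adjusted p = 0.857 with an estimated correlation). Of the B and plasma cell markers, 1 of 7 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.393, adjusted p = 0.6 with an estimated correlation). The panel gene Mki67 (1.29 ± 0.45, adjusted p = 0.029) rose. Pancreas genes were higher in the controls: 0 of 13 rose and 12 fell (0 and 13 adjusted over the list alone, camera adjusted p = 0.00373, adjusted p = 0.577 with an estimated correlation), led by pancreatic lipase Pnlip (-7.14 ± 2.24). The list's mean log2 CPM was highest in control animals 22 (3.40) and 23 (2.71). 1 of 5 adipose tissue genes rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.168, adjusted p = 0.597 with an estimated correlation). The panel genes Afp (-0.07 ± 0.26), Gpc3 (0.09 ± 0.29) and Cdkn1a (-0.48 ± 0.45) did not pass the test (lowest adjusted p = 0.436). Trem2 did not pass without animal 23, 171 or 92 (1.02, 1.11 and 1.08). Gpnmb did not pass without animal 11, 23, 171, 92, 251 or 252 (1.2, 0.89, 0.89, 1.07, 1.09 and 1.02). Mki67 did not pass without animal 22, 23, 171, 101 or 252 (1.25, 1.07, 1.09, 1.21 and 1.08). Gpnmb was at 1.82 without animal 21.

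1 of 20 glucose metabolism genes in males at 60 weeks rose and 11 fell (1 and 12 adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.0774 with an estimated correlation), led by G6pc (-1.69 ± 0.33) and Pck1 (-0.81 ± 0.24), enzymes of glucose output. 0 of 19 methionine and one-carbon metabolism genes rose and 13 fell (0 and 13 adjusted over the list alone, camera adjusted p = 1.34e-08, adjusted p = 0.0774 with an estimated correlation), led by Ftcd (-0.64 ± 0.11). 1 of 23 bile acid synthesis and transport genes rose and 10 fell (1 and 12 adjusted over the list alone, camera adjusted p = 9.24e-05, adjusted p = 0.29 with an estimated correlation), led by the repressor Nr0b2 (-1.09 ± 0.30). 0 of 23 nuclear oxidative phosphorylation genes rose and 12 fell (0 and 14 adjusted over the list alone, camera adjusted p = 1.62e-05, adjusted p = 0.549 with an estimated correlation), led by Ndufb8 (-0.43 ± 0.11). Cidec rose by 3.10 ± 0.58 and Sqle by 1.27 ± 0.46 (adjusted p = 0.0327), while Gdf15, a stress cytokine, fell by a log2 change of -1.34 ± 0.34. The panel genes Cyp7a1 (0.47 ± 0.57), Scd1 (-0.15 ± 0.17), Fasn (-0.61 ± 0.37), Cd36 (0.35 ± 0.26), Cyp4a14 (0.45 ± 0.59), Fgf21 (0.50 ± 0.31), Cyp4a12a (0.20 ± 0.25), Hsd3b5 (-1.17 ± 0.55) and Mup20 (-0.52 ± 0.30) did not pass the test (lowest adjusted p = 0.103). Sqle did not pass without animal 22, 23, 171, 101 or 251 (1.19, 1.16, 1.25, 1.13 and 0.99). Gdf15 did not pass without animal 171 (-0.52, adjusted p = 0.204). Fgf21 passed without animal 91 (0.76, adjusted p = 0.0311), as did Hsd3b5 without animal 91 (-2.96, adjusted p = 1.42e-05), as did Mup20 without animal 91 (-0.79, adjusted p = 0.0438).

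In females at 20 weeks, the xenobiotic cytochrome Cyp3a11 rose from 4.94 ± 2.65 to 205 ± 108 CPM, a log2 fold change of 5.36 ± 0.54. Gpnmb rose by 4.37 ± 0.93, Muc13 by 4.37 ± 0.98 and Mmp12 by 4.25 ± 0.66. Sprr1a, with 3 counts over the control group, was higher on the HF/HS diet by a ratio of 197 with an exact 95% counting interval of 67.1 to 959. Decreases included Prtn3 (-6.77 ± 1.69), Pcdh20 (-4.64 ± 0.85), Shbg (-4.62 ± 0.54), Crybb3 (-4.49 ± 0.98) and Enho (-3.71 ± 0.67). Of these 10 genes, the highest adjusted p was 0.00292 (edgeR). In total 1351 genes rose and 1521 fell, the lowest number of the 6 diet comparisons as reported, and a fit of these 10 libraries alone called 1428 in place of 2872. Prtn3 did not pass without animal 383 (-4.24, adjusted p = 0.0896). Crybb3 did not pass without animal 383 (-2.51, adjusted p = 0.0511).

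0 of 23 cholesterol synthesis and uptake genes in females at 20 weeks rose and 17 fell (0 and 21 adjusted over the list alone, camera adjusted p = 1.27e-13, adjusted p = 0.339 with an estimated correlation), led by Idi1 (-1.76 ± 0.28) and Cyp51 (-1.57 ± 0.24) and with Sqle (-1.48 ± 0.45). 12 of 19 lipid droplet and fatty acid uptake genes rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.53e-08, adjusted p = 0.202 with an estimated correlation), led by Cidec (3.76 ± 0.67) and with Cd36 (1.17 ± 0.27). 12 of 28 fatty acid oxidation genes rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 1.06e-05, adjusted p = 0.647 with an estimated correlation), led by the peroxisomal thiolase Acaa1b (1.52 ± 0.29). 0 of 30 ribosomal proteins rose and 28 fell (0 and 29 adjusted over the list alone, camera adjusted p = 2.51e-26, adjusted p = 0.147 with an estimated correlation), led by Rpl3 (-0.52 ± 0.08). 5 of 20 xenobiotic cytochromes rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.635 with an estimated correlation). Collagen Col1a1 (1.46 ± 0.45, adjusted p = 0.0159) rose. Of the neutrophil markers, 0 of 5 rose and 0 fell (0 and 0 adjusted over the list alone), of the erythroid markers 0 of 4 rose and 0 fell (0 and 0 adjusted over the list alone), and of the gut and gallbladder epithelium markers 1 of 3 rose and 2 fell (1 and 2 adjusted over the list alone), the last pair of lists being too short for camera. 3 of 23 male-biased liver genes rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.917, adjusted p = 0.969 with an estimated correlation), among them Hsd3b5 (-3.19 ± 0.78) and Cyp4a12a (2.41 ± 0.42). The panel genes Cyp7a1 (1.14 ± 0.56), Scd1 (0.46 ± 0.17), Fasn (0.27 ± 0.37), Cyp4a14 (1.08 ± 0.49), Fgf21 (0.28 ± 0.31), Timp1 (1.5 ± 0.76), Trem2 (1.44 ± 0.56), Spp1 (0.33 ± 0.27), Afp (-0.78 ± 0.33), Gpc3 (-0.25 ± 0.29), Mki67 (0.99 ± 0.44), Cdkn1a (0.92 ± 0.46), Gdf15 (0.37 ± 0.36) and Mup20 (0.61 ± 0.31) did not pass the test (lowest adjusted p = 0.0502). Sqle did not pass without animal 381 or 302 (-1.22 and -1.25). Col1a1 did not pass without animal 422 (1.2, adjusted p = 0.0695). Cyp7a1 passed without animal 383 (1.86, adjusted p = 0.0205), as did Scd1 without animal 381 or 302 (0.65 and 0.55), as did Cyp4a14 without animal 382 (1.58, adjusted p = 0.0291), as did Mki67 without animal 203 (1.42, adjusted p = 0.0261). Cdkn1a passed without animal 381 (1.84, adjusted p = 0.00321).

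In females at 40 weeks, Cyp3a11 rose from 3.80 ± 2.58 to 550 ± 368 CPM (7.15 ± 0.59) and Gpnmb from 0.240 ± 0.124 to 31.8 ± 14.6 CPM (7.04 ± 0.73). Cyp7a1 rose by 3.82 ± 0.63. Krt20, an epithelial keratin, had 0 counts in all 5 controls and was at least 50.5-fold higher, against a floor of 3 counts over the group. Sprr1a, with 2 counts over the controls, was higher by a ratio of 332 with an exact 95% counting interval of 91.8 to 2749. Muc13 rose by 7.28 ± 0.90. The neutrophil protease Prtn3 fell by a log2 change of -6.78 ± 1.47, beside Megf11 (-6.29 ± 0.59) and Crybb3 (-5.96 ± 1.12). Rnase2a, with 3 counts over the HF/HS group, was higher in the controls by a ratio of 78.1 with an exact 95% counting interval of 26.3 to 382. The highest adjusted p of these genes was 0.00671 (edgeR). In total 2127 genes rose and 1890 fell, against 1907 and 2332 with small RNA genes removed before scaling. Limma voom with sample quality weights called 6134 in place of 4017.

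0 of 23 cholesterol synthesis and uptake genes in females at 40 weeks rose and 16 fell (0 and 18 adjusted over the list alone, camera adjusted p = 3.14e-08, adjusted p = 0.323 with an estimated correlation), led by Sqle (-1.21 ± 0.44). 9 of 19 lipid droplet and fatty acid uptake genes rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.323 with an estimated correlation), led by Cidea (5.71 ± 1.15) and Cidec (5.0 ± 0.69) and with Cd36 (0.96 ± 0.27). Acute phase genes moved down: 0 of 21 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 5.18e-06, adjusted p = 0.393 with an estimated correlation), led by serum amyloid Saa2 (-3.07 ± 0.89) and Saa1 (-2.88 ± 0.83). 1 of 20 unfolded protein and integrated stress response genes rose and 14 fell (1 and 15 adjusted over the list alone, camera adjusted p = 8.32e-06, adjusted p = 0.217 with an estimated correlation), led by Atf3 (1.98 ± 0.37), which rose, and Chac1 (-1.66 ± 0.37), which fell. 13 of 22 NRF2 and glutathione genes rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 9.46e-07, adjusted p = 0.217 with an estimated correlation), led by Gsta1 (4.66 ± 0.79) and Slc7a11 (3.77 ± 0.62). 5 of 17 circadian clock genes rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.975, adjusted p = 0.998 with an estimated correlation), led by Dbp (3.77 ± 0.81), a clock output gene, with a median of 0.06 while camera pointed down. The major urinary protein gene Mup20 (0.95 ± 0.31, adjusted p = 0.0189) rose. The panel genes Scd1 (0.16 ± 0.17), Fasn (0.02 ± 0.37), Cyp4a14 (1.01 ± 0.50), Fgf21 (0.41 ± 0.30), Cyp4a12a (1.35 ± 0.64) and Hsd3b5 (-2.60 ± 2.02) did not pass the test (lowest adjusted p = 0.109). Sqle did not pass without animal 452, 461, 473 or 483 (-1.19, -1.16, -1.07 and -1.09). Mup20 did not pass without animal 453 or 482 (0.86 and 0.77). Cyp4a14 passed without animal 453 (1.41, adjusted p = 0.0487), as did Cyp4a12a without animal 452 (2.17, adjusted p = 0.0331).

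0 of 15 hepatocyte markers in females at 40 weeks rose and 10 fell (0 and 13 adjusted over the list alone, camera adjusted p = 4.25e-12, adjusted p = 0.00647 with an estimated correlation), led by Serpina1c (-0.95 ± 0.10). Of the bile duct cell markers, 11 of 13 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.82e-11, adjusted p = 0.0352 with an estimated correlation), led by Krt23 (4.37 ± 0.68). Both calls held with the estimated correlation. 0 of 10 Kupffer cell markers rose and 5 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.498 with an estimated correlation), led by the scavenger receptors Marco (-1.88 ± 0.62) and Cd163 (-1.63 ± 0.36). Timp1 and Col1a1 rose by 3.61 ± 0.59 and 3.55 ± 0.46. Trem2 and Spp1 rose by 2.66 ± 0.46 and 1.82 ± 0.27. Pancreas genes were higher in the controls: 0 of 13 rose and 13 fell (0 and 13 adjusted over the list alone, camera adjusted p = 0.0719, adjusted p = 0.777 with an estimated correlation), and the list's mean log2 CPM was highest in control animal 463 (5.38). The panel genes Afp (0.14 ± 0.33), Gpc3 (-0.14 ± 0.29), Mki67 (1.02 ± 0.43), Cdkn1a (-1.05 ± 0.46) and Gdf15 (-0.16 ± 0.35) did not pass the test (lowest adjusted p = 0.0713). Marco did not pass without animal 461 (-1.41, adjusted p = 0.112). Mki67 passed without animal 453 (1.73, adjusted p = 0.00321).

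In females at 60 weeks, Ubd rose by 6.91 ± 0.81, Cyp3a11 from 5.68 ± 0.650 to 573 ± 306 CPM (6.66 ± 0.57) and Gpnmb from 0.927 ± 0.646 to 42.5 ± 24.5 CPM (5.52 ± 0.59), beside the melatonin receptor Mtnr1a (5.33 ± 0.49) and the ciliary factor Foxj1 (5.30 ± 0.53). Pcdh20 and Sult3a1 changed by -7.09 ± 0.89 and -4.98 ± 0.53. A2m changed by -9.76 ± 1.75, with a control mean of 393 ± 864 CPM that rested on animal 31. Rnase2a, with 3 counts over the HF/HS group, was higher in the controls by a ratio of 98.2 with an exact 95% counting interval of 33.2 to 480. The highest adjusted p of these genes was 0.00251 (edgeR). In total 2751 genes rose and 2495 fell, against 2490 and 3256 with small RNA genes removed. A2m was at -3.86 without animal 31.

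27 of 32 extracellular matrix and fibrosis genes in females at 60 weeks rose and 1 fell (27 and 1 adjusted over the list alone, camera adjusted p = 5.52e-18, adjusted p = 0.126 with an estimated correlation), led by Mmp12 (4.05 ± 0.53) and Col1a1 (3.96 ± 0.44) and with Timp1 (2.97 ± 0.53). 12 of 13 bile duct cell markers rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.86e-14, adjusted p = 0.0148 with an estimated correlation), led by Cldn4, which had 3 counts over the controls and was higher by a ratio of 30.2 with an exact 95% counting interval of 10.1 to 149. 0 of 15 hepatocyte markers rose and 12 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.09e-09, adjusted p = 0.0148 with an estimated correlation), led by the tyrosine aminotransferase Tat (-1.47 ± 0.34). Both calls held with the estimated correlation. 10 of 14 lipid-associated macrophage markers rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 6.7e-10, adjusted p = 0.126 with an estimated correlation), with Trem2 (3.12 ± 0.45) and Spp1 (2.63 ± 0.27). 16 of 25 cell cycle genes rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 8.12e-05, adjusted p = 0.38 with an estimated correlation), with Bub1 (3.60 ± 0.59) and Mki67 (1.68 ± 0.45). 15 of 20 fetal liver and liver tumour genes rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.142 with an estimated correlation), led by H19 (3.87 ± 0.58) and Sox4 (3.39 ± 0.32), while Gpc3 (-1.17 ± 0.28, adjusted p = 0.000814) fell and Afp (0.52 ± 0.35, adjusted p = 0.242) did not pass the test. Cdkn1a and Gdf15, of the p53 and senescence list, fell, by log2 changes of -1.26 ± 0.46 and -1.18 ± 0.35. Cdkn1a did not pass without animal 192, 112 or 122 (-1.09, -1.2 and -1.13). Afp passed without animal 191 (0.94, adjusted p = 0.0479).

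Female-biased liver genes moved down in females at 60 weeks: 0 of 27 rose and 14 fell (0 and 16 adjusted over the list alone, camera adjusted p = 0.000159, adjusted p = 0.38 with an estimated correlation). 1 of 19 fatty acid synthesis genes rose and 8 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.573 with an estimated correlation), although the largest change was a rise in the desaturase Scd2 (4.95 ± 0.41), followed by a fall in Pnpla3 (-2.45 ± 0.59). 2 of 23 bile acid synthesis and transport genes rose and 14 fell (2 and 14 adjusted over the list alone, camera adjusted p = 0.000295, adjusted p = 0.286 with an estimated correlation), although Cyp7a1 (2.0 ± 0.58, adjusted p = 0.00562) rose. Cidec rose by 4.34 ± 0.66 and Mup20 by 1.52 ± 0.32. The panel genes Sqle (-1.01 ± 0.44), Scd1 (0.14 ± 0.17), Fasn (-0.49 ± 0.37), Cd36 (0.35 ± 0.26), Cyp4a14 (-0.16 ± 0.48), Fgf21 (0.32 ± 0.30), Cyp4a12a (0.62 ± 0.55) and Hsd3b5 (-3.89 ± 2.25) did not pass the test (lowest adjusted p = 0.0686). The panel gene Cyp2b9 had too few counts to be tested in any comparison.

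**Figure D2:**
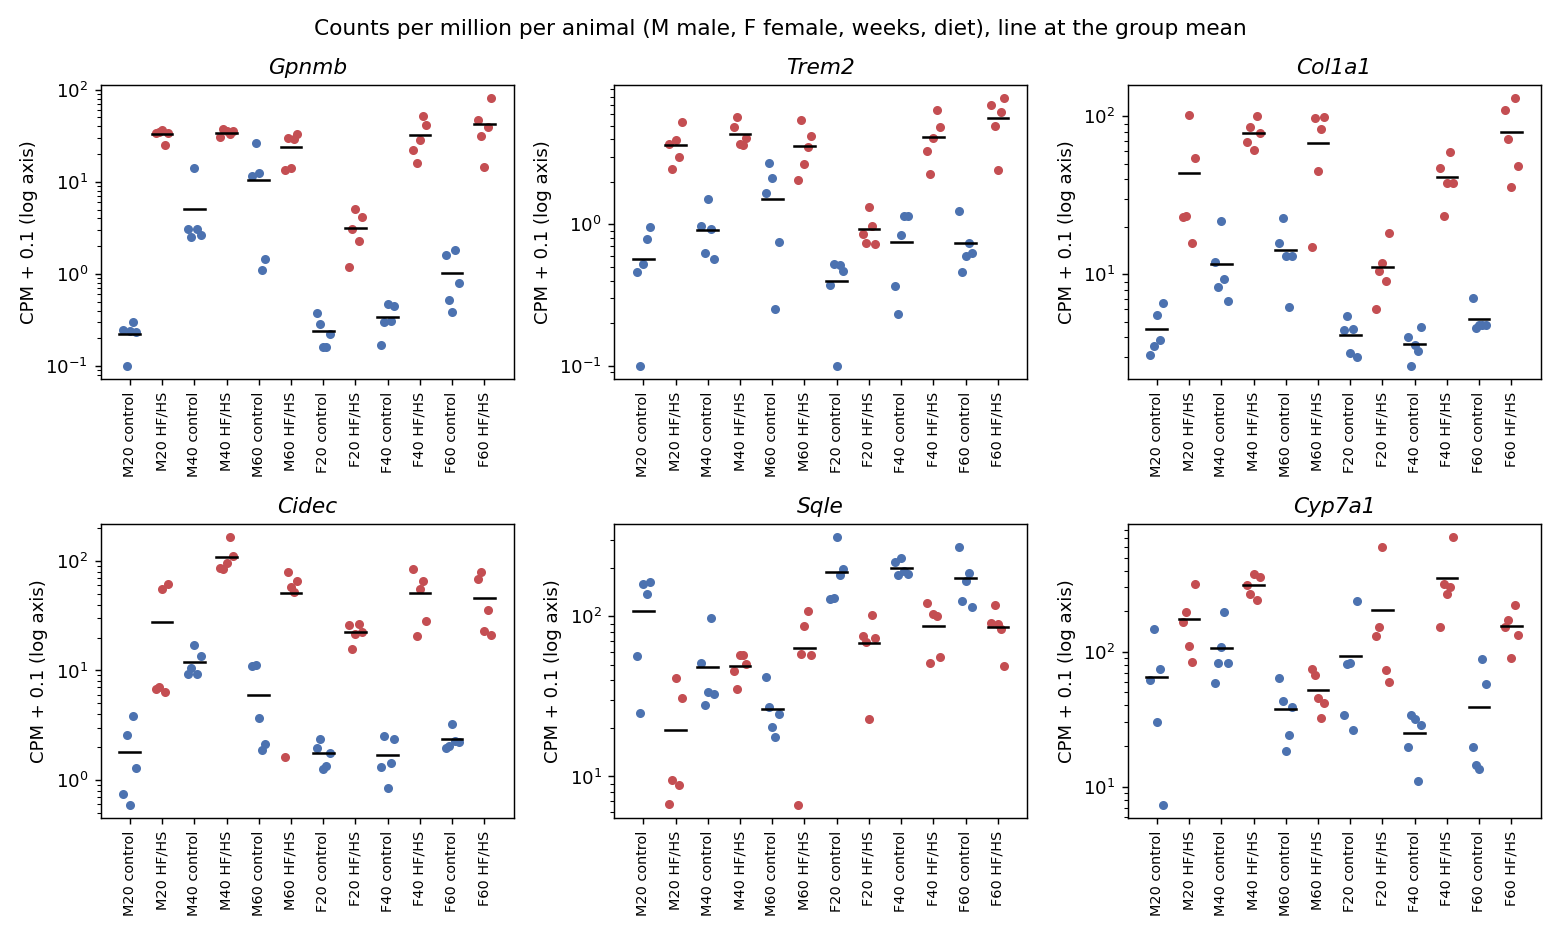
Each point is 1 animal's CPM plus 0.1 on a log axis (y) in the 12 groups (x, M male, F female, weeks, diet), with a line at the mean of 5 animals (blue control, red HF/HS), for Gpnmb, Trem2, Col1a1, Cidec, Sqle and Cyp7a1. Cidec, Gpnmb and Col1a1 were called higher on the HF/HS diet in all 6 comparisons.

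**Figure D3:**
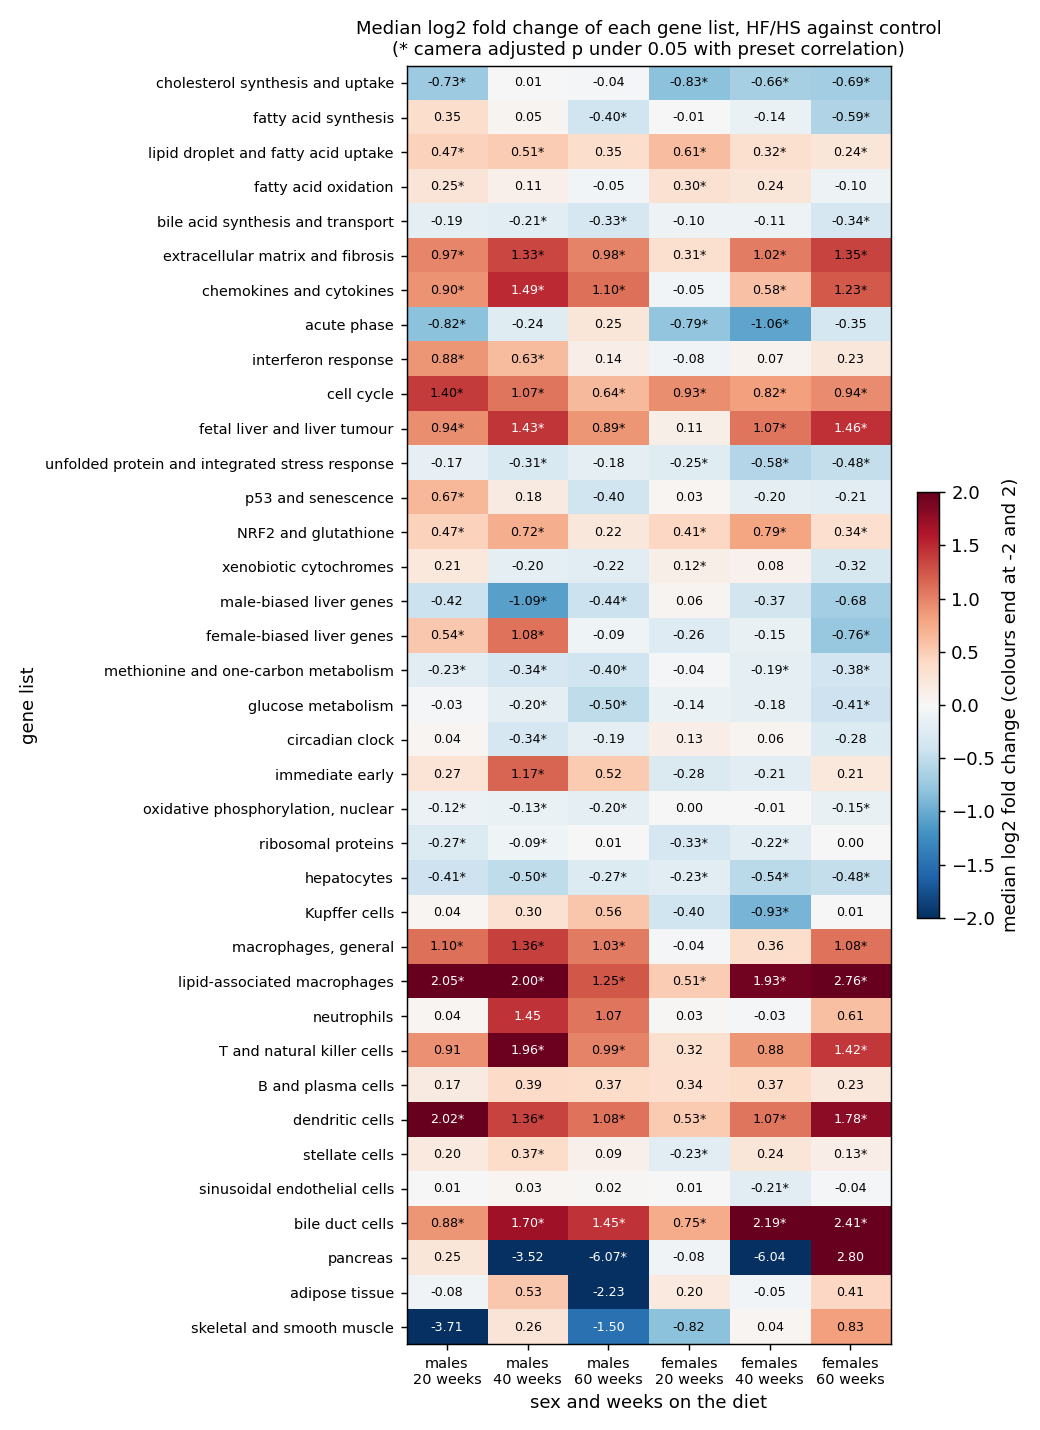
Cells give the median log2 fold change of each gene list (y axis) on the HF/HS diet in each sex and duration (x axis), coloured from -2 to 2, with an asterisk at a camera adjusted p under 0.05 with preset correlation. Extracellular matrix and fibrosis, lipid-associated macrophage and bile duct lists carried asterisks in all 6 columns. Of these, only the bile duct list passed with an estimated correlation, in females at 40 and 60 weeks.

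Across the 6 diet comparisons, which share no library, 185 genes were called higher and 124 lower in all 6. By the smallest of their 6 log2 fold changes, the leading higher genes were Ubd (smallest 3.14, chromosome 17 at 37193892 to 37196095 in mm10), Cidec (3.10, chromosome 6 at 113424634 to 113435760), Muc13 (2.96, chromosome 16 at 33794037 to 33819934) and the chemokine Cxcl5 (2.91). Pcdh20, a protocadherin on chromosome 14 at 88464743 to 88471396, fell in all 6, with -2.94 or lower on the log2 scale, followed by the citrate and succinate carrier Slc13a2 (-1.25). These 6 were chosen by their rank in all 6 comparisons after the values were seen. Between the sexes, 590 genes were higher in both at 20 weeks, against 194 expected of independent lists, 1346 at 40 weeks, against 451, and 1623 at 60 weeks, against 426. Calls in opposite directions numbered 2, 36 and 17.

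The difference of the diet effect between the sexes at 20 weeks asked whether females responded unlike males. The diet effect was higher in females for Palm2 (3.59 ± 0.83), Cyp3a11 (3.20 ± 0.66), Cyp4a12b (2.69 ± 0.46), Myom2 (2.56 ± 0.55) and Elovl3 (2.23 ± 0.55) and lower for Bmp8b (-4.46 ± 1.0), Slc22a27 (-3.20 ± 0.74), Megf11 (-3.14 ± 0.72), Atp2b2 (-2.72 ± 0.61) and Ddah1 (-2.70 ± 0.39) (female minus male, log2, highest adjusted p = 0.04, edgeR). 0 of 15 p53 and senescence genes were higher and 2 lower (0 and 8 adjusted over the list alone, camera adjusted p = 1.58e-08, adjusted p = 0.0338 with an estimated correlation), a call that held, led by Phlda3 (-2.09 ± 0.49) and Eda2r (-1.85 ± 0.42). 0 of 20 interferon response genes were higher and 4 lower (0 and 14 adjusted over the list alone, camera adjusted p = 6.67e-15, adjusted p = 0.112 with an estimated correlation), led by Gbp3 (-1.79 ± 0.38). In total 24 genes were higher and 65 lower. A fit of these 20 libraries alone called 28, and 4 of 40 splits, the real one included, gave at least as many, so chance stays open. Single libraries moved the 89 calls, from 35 without male control animal 182 to 598 without male control animal 373. It was 37 without animal 181, 39 without 413, 46 without 203, 48 without 421, 49 without 301, 50 without 411 and 54 without 381. Palm2 did not pass without animal 181, 182, 413, 203, 382, 301 or 421 (3.19 to 3.51). Elovl3 did not pass without animal 181, 182, 371, 372, 271, 411, 413, 203, 381, 382, 383, 301, 421 or 422 (2.02 to 2.29). Bmp8b did not pass without animal 413 (-3.67, adjusted p = 0.0804). Slc22a27 did not pass without animal 181, 182, 371, 372, 411 or 413 (-3.17, -2.91, -3.00, -2.95, -2.75 and -2.97). Megf11 did not pass without animal 182 or 261 (-2.96 and -2.92). Atp2b2 did not pass without animal 182, 411 or 413 (-2.51, -2.50 and -2.42). Phlda3 did not pass without animal 181, 182, 413, 203, 381 or 301 (-1.94, -2.03, -2.07, -1.71, -2.02 and -2.04). Eda2r did not pass without animal 181, 271, 203 or 301 (-1.81, -1.66, -1.5 and -1.73).

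At 40 weeks, the diet effect was higher in females for Cyp3a11 (5.29 ± 0.69) and Myom2 (4.68 ± 0.68) and lower for Megf11 (-4.43 ± 0.90), Tcf24 (-4.40 ± 0.73), Slc22a26 (-4.05 ± 0.93) and Wisp2 (-3.74 ± 0.75) (female minus male, highest adjusted p = 0.00879, edgeR). Mtnr1a, Omd and Sstr2 also came under the naming rule, with 3 counts or fewer over the female controls, so no fold is given. 0 of 10 Kupffer cell markers were higher and 3 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.000404, adjusted p = 0.334 with an estimated correlation), led by Marco (-3.59 ± 0.94). 4 of 17 circadian clock genes were higher and 0 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00263, adjusted p = 0.324 with an estimated correlation), led by Dbp (3.95 ± 1.01). Of the female-biased liver genes, 0 of 27 were higher and 8 lower (1 and 11 adjusted over the list alone, camera adjusted p = 7.11e-10, adjusted p = 0.324 with an estimated correlation). In total 215 genes were higher and 319 lower, against 2401 in all in a fit of these 20 libraries alone. With a clock score as a covariate, chosen after seeing the data, the count fell to 139 from 534 and the share of higher calls was 56.1% in place of 40.3%. Leaving out 1 library gave 262 without animal 461, 266 without 493, 315 without 512, 316 without 473, 346 without 463 and 354 without 521. Marco did not pass without animal 512 or 461 (-2.73 and -3.11).

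At 60 weeks, the diet effect was higher in females for Cyp3a11 (5.02 ± 0.67), Mtnr1a (4.73 ± 0.59), Gpnmb (4.35 ± 0.75), Omd (4.0 ± 0.68) and Lrtm2 (3.18 ± 0.76) and lower for Scara5 (-5.21 ± 1.22), Cacna1h (-4.50 ± 0.95) and Sult4a1 (-4.37 ± 1.10) (female minus male, highest adjusted p = 0.0342, edgeR). 0 of 27 female-biased liver genes were higher and 1 lower (0 and 4 adjusted over the list alone, camera adjusted p = 2.67e-08, adjusted p = 0.414 with an estimated correlation). In total 60 genes were higher and 61 lower, against 68 in all in a fit of these 20 libraries alone and 78 without female HF/HS animal 122. Lrtm2 did not pass without animal 21, 42 or 122 (2.42, 2.96 and 2.89). Scara5 did not pass without animal 31 (-0.28, adjusted p = 0.965). Sult4a1 did not pass without animal 21, 22, 92, 101, 251, 252, 191 or 122 (-4.40 to -3.83).

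From 20 to 60 weeks the diet effect in males rose for Prtn3 (10.31 ± 2.41), Orm1 (5.39 ± 1.42) and Cxcl14 (5.10 ± 1.33). It fell for Gpnmb (-6.83 ± 1.02), A4gnt (-5.03 ± 0.84), Mmp12 (-4.96 ± 0.81) and Mogat1 (-4.59 ± 0.93). The highest adjusted p was 0.0115 (edgeR). Controls rose in Gpnmb, A4gnt and Mogat1 (below). HF/HS Gpnmb was 25.3 to 36.3, then 13.2 to 33.1 CPM. Trat1 and Sprr1a had a group at 0 counts, so no fold is given. 0 of 15 p53 and senescence genes rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 1.54e-09, adjusted p = 0.0122 with an estimated correlation), led by Gdf15 (-3.37 ± 0.52) and Eda2r (-2.66 ± 0.42). List scores rose in controls (3.43 to 3.91, then 4.31 to 4.85), not on the HF/HS diet (4.22 to 4.65). Of the acute phase genes, 10 of 21 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 4.09e-05, adjusted p = 0.567 with an estimated correlation). Of its 20 week controls, only animals 371 and 373 lay high. In total 736 genes rose and 576 fell, or 142 and 183 with these 20 libraries fitted alone. Of 40 splits, 4, the real one included, gave at least as many, so chance stays open. Orm1 did not pass without animal 373 (4.0, adjusted p = 0.0609).

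In females, it rose for the muscle genes Ckm (6.54 ± 2.36) and Myh2 (6.35 ± 2.33) and for H19 (4.08 ± 0.83), Osbpl3 (3.62 ± 0.89) and Usp43 (3.40 ± 0.91), and fell for Cacna1h (-4.80 ± 1.10) and Malrd1 (-4.59 ± 0.63) (60 minus 20 weeks, highest adjusted p = 0.0481, edgeR). Sprr1a and Rnase2a also came under the rule, with no fold as a group had 3 counts or fewer. 19 of 32 extracellular matrix and fibrosis genes rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 9.02e-11, adjusted p = 0.333 with an estimated correlation), led by Col1a1 (2.50 ± 0.62) and Mmp2 (2.45 ± 0.45). 11 of 13 general macrophage markers rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 2.37e-07, adjusted p = 0.344 with an estimated correlation), led by Lyz2 (1.89 ± 0.35). Of the ribosomal proteins, 24 of 30 rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 1.05e-13, adjusted p = 0.252 with an estimated correlation). In total 1363 genes rose and 1287 fell. Neither Ckm nor Myh2 passed without animal 203 (4.52 and 3.73) or 112 (4.2 and 3.99). Those animals led these groups in muscle list score (2.83 and 2.39). Nor did Ckm or Myh2 without 292, 302, 421, 422, 32, 42 or 191 (5.99 to 6.37). Nor did Ckm without 31 (6.53) or Myh2 without 192 (6.91) or 281 (6.44). Usp43 did not pass without animal 202 (2.92, adjusted p = 0.0549).

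Controls at 60 and 20 weeks were compared for changes with age. Animal numbers ran mostly in other ranges at 60 than at 20 weeks, so cohort is not separated from age here or in the changes with duration. With the range as a covariate, 4987 genes passed in males and 4005 in females. In control males, Gpnmb rose from 0.123 ± 0.0732 to 10.5 ± 10.3 CPM (6.37 ± 0.88), beside Hao2 (5.27 ± 1.04), A4gnt (4.44 ± 0.64), Mogat1 (4.03 ± 0.77) and Mapk10 (3.79 ± 0.71), and A2m (-8.19 ± 2.32), Moxd1 (-4.78 ± 0.99), Ces4a (-4.56 ± 0.73) and Cyp2c69 (-4.22 ± 0.48) fell (highest adjusted p = 0.00455, edgeR). Trat1 had 0 counts in all 5 animals at 60 weeks and was at least 733-fold lower than at 20 weeks, against a floor of 3 counts over the group. 0 of 30 ribosomal proteins rose and 30 fell (0 and 30 adjusted over the list alone, camera adjusted p = 3.86e-27, adjusted p = 0.0668 with an estimated correlation), led by Rps7 (-0.68 ± 0.08). 12 of 15 p53 and senescence genes rose and 0 fell (12 and 1 adjusted over the list alone, camera adjusted p = 4.57e-06, adjusted p = 0.0668 with an estimated correlation), led by Gdf15 (3.36 ± 0.39) and Phlda3 (2.26 ± 0.35). In total 2602 genes rose and 2610 fell, and a fit of these 10 libraries alone called 2597 in place of 5212. A2m did not pass without animal 373 (-2.57, adjusted p = 0.659). Moxd1 was at -8.19 without animal 171.

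In control females, Cacna1h (5.06 ± 0.60), Col22a1 (2.87 ± 0.45), Ciart (2.64 ± 0.63) and Gprc5b (2.63 ± 0.65) rose from 20 to 60 weeks and Hsd3b5 (-4.17 ± 0.88), Ccr3 (-2.78 ± 0.39), Cyp2c54 (-2.26 ± 0.40), Nox4 (-1.82 ± 0.53) and Cela1 (-1.54 ± 0.44) fell (highest adjusted p = 0.00783, edgeR). Sprr1a, with 3 counts over the group at 20 weeks, was higher at 60 weeks by a ratio of 62.5 with an exact 95% counting interval of 21.0 to 306. 0 of 30 ribosomal proteins rose and 24 fell (0 and 26 adjusted over the list alone, camera adjusted p = 2.71e-15, adjusted p = 0.921 with an estimated correlation), led by Rps7 (-0.56 ± 0.08). Of the p53 and senescence genes, 8 of 15 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00996, adjusted p = 0.921 with an estimated correlation), led by Cdkn1a (2.0 ± 0.47). In total 1955 genes rose and 1898 fell, and a fit of these 10 libraries alone called 1845 in place of 3853.

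Females and males were compared on each diet, over 15 animals of each sex. On the control diet, the female-biased genes A1bg, Cyp3a16 and Sult2a1 were higher in females, by 12.41 ± 0.62, 12.33 ± 0.34 and 11.78 ± 0.18, beside Xist (13.55 ± 0.18), and Moxd1 was lower (-11.37 ± 1.02), beside the Y-linked Ddx3y (-11.00 ± 0.35) and Kdm5d (-10.64 ± 0.17). Sult2a3, with 2 counts over the males, was higher in females by a ratio of 10321 with an exact 95% counting interval of 2857 to 85226. The Y-linked Eif2s3y and Uty, which females lack, also came under the rule. 27 of 27 female-biased liver genes were higher and 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 6.84e-81, adjusted p = 7.87e-08 with an estimated correlation). Of the male-biased liver genes, 0 of 23 were higher and 22 lower (0 and 23 adjusted over the list alone, camera adjusted p = 4.45e-45, adjusted p = 0.000212 with an estimated correlation). 20 of 23 cholesterol synthesis and uptake genes were higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 9.08e-05, adjusted p = 0.93 with an estimated correlation), led by Sqle (1.86 ± 0.26). In total 3365 genes were higher and 3580 lower in females (edgeR adjusted p under 0.05).

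On the HF/HS diet, Sult2a1, Cyp3a16 and Sult2a2 were higher in females, by 11.57 ± 0.18, 11.13 ± 0.35 and 10.73 ± 0.18, beside Xist (13.35 ± 0.18), and Moxd1 was lower (-10.39 ± 1.10), beside Ddx3y (-11.24 ± 0.34). 26 of 27 female-biased liver genes were higher and 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 2.47e-89, adjusted p = 2.47e-07 with an estimated correlation). Of the male-biased liver genes, 0 of 23 were higher and 23 lower (0 and 23 adjusted over the list alone, camera adjusted p = 7.16e-62, adjusted p = 8.73e-06 with an estimated correlation). 0 of 20 unfolded protein and integrated stress response genes were higher and 15 lower (0 and 15 adjusted over the list alone, camera adjusted p = 6.02e-05, adjusted p = 0.622 with an estimated correlation), led by the asparagine synthetase Asns (-1.89 ± 0.25). In total 2076 genes were higher and 2535 lower in females.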

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

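The tests of the clock, of single libraries and of the pancreas for the acute phase pattern, of animal 91, of other splits for the 6 diet comparisons and of the libraries kept in splits were chosen after the result was seen. Libraries far from the other 4 of their group were sought by Dixon's ratio in 1185 sets of 5 values, for the genes named, the list scores and the totals, and 108 were found where chance gives about 1 in 20, or 59.2. The outlying values follow, in CPM or as the mean log2 CPM of a list.

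In males on the control diet at 20 weeks, animal 182 had Gpnmb 0. Animal 373 had Cd36 182, Cyp4a12a 117, Hsd3b5 51.1, Spp1 25.3, Elovl3 62.7, A2m 126, A1bg 2.26, Ddx3y 93.5, extracellular matrix and fibrosis list 3.58, male-biased liver genes list 6.64, female-biased liver genes list 2.80 and pancreas list 1.27. Animal 371 had Cdkn1a 134. Animal 372 had total count 10923963. In males on the HF/HS diet at 20 weeks, animal 412 had Gpnmb 25.3. Animal 261 had ribosomal proteins list 6.85. Animal 413 had hepatocytes list 9.55. In males on the control diet at 40 weeks, animal 501 had Dnah17 2.65, Mmp12 16.7, Timp1 0.443, Gpnmb 14.0, Ccl22 0.147, Cyp3a11 701 and lipid-associated macrophages list 2.82. Animal 502 had Cyp4a12a 476 and pancreas list 1.35. Animal 493 had macrophages, general list 3.66. Animal 492 had skeletal and smooth muscle list 1.27. In males on the HF/HS diet at 40 weeks, animal 521 had Dnah17 0.438. Animal 513 had Gpc3 1.89. Animal 512 had Fosb 0.0651, NRF2 and glutathione list 5.25, Kupffer cells list 5.24 and stellate cells list 4.94. Animal 522 had interferon response list 3.36. In males on the HF/HS diet at 60 weeks, animal 91 had Timp1 0.126, Spp1 19.5, Mki67 4.80, Pnlip 0.316, Cidec 1.52, Sqle 6.57, Scd1 8973, Fasn 1317, Fgf21 2.15, Mup20 1519, Cyp3a11 332, Lrtm2 1.39, Moxd1 283, fatty acid synthesis list 8.19, lipid droplet and fatty acid uptake list 4.47, cell cycle list 1.12, fetal liver and liver tumour list 2.20, male-biased liver genes list 8.01 and female-biased liver genes list 0.869. Animal 101 had skeletal and smooth muscle list 0.977. In males on the control diet at 60 weeks, animal 171 had Afp 4.89 and Mtnr1a 4.53. Animal 11 had Fgf21 9.60 and Scara5 29.7. In females on the HF/HS diet at 20 weeks, animal 302 had Idi1 4.51, Cyp51 36.2, Sqle 22.7, Fasn 1595, cholesterol synthesis and uptake list 5.47 and fatty acid synthesis list 8.67. Animal 292 had Cd36 647. Animal 422 had bile acid synthesis and transport list 7.98 and female-biased liver genes list 6.25. In females on the control diet at 20 weeks, animal 381 had Trem2 0. Animal 383 had A1bg 90.4, Sult2a1 319, bile acid synthesis and transport list 7.80 and sinusoidal endothelial cells list 5.61. Animal 382 had Ddx3y 0.0591. Animal 202 had hepatocytes list 10.2. In females on the control diet at 40 weeks, animal 453 had Sprr1a 0.133 and cell cycle list 2.41. Animal 452 had Megf11 3.29, Rnase2a 0.134 and p53 and senescence list 4.60. In females on the HF/HS diet at 40 weeks, animal 473 had Timp1 0.972, Sult2a1 484 and methionine and one-carbon metabolism list 8.50. Animal 481 had Moxd1 0.0471. Animal 471 had Ddx3y 0.179. Animal 482 had skeletal and smooth muscle list 1.65. In females on the control diet at 60 weeks, animal 31 had Col1a1 7.02, Sox4 2.08, Mup20 40.0, Scara5 107, Malrd1 0.501, A1bg 62.1, Sult2a1 329, Kdm5d 0.215, Sult2a3 30.3, unfolded protein and integrated stress response list 6.12, female-biased liver genes list 6.53, oxidative phosphorylation, nuclear list 6.77 and ribosomal proteins list 6.61. Animal 42 had Cidec 3.16 and stellate cells list 4.49. Animal 32 had pancreas list -0.530. In females on the HF/HS diet at 60 weeks, animal 281 had Mup20 22.3 and Cacna1h 0.452. Animal 112 had Moxd1 0.0565. Animal 121 had glucose metabolism list 7.65. Animal 111 had B and plasma cells list 0.927.

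By the interaction test, the difference of the diet effect between sexes at 20 weeks held 89 called genes, with log2 values of Palm2 3.59, Cyp3a11 3.20, Cyp4a12b 2.69, Myom2 2.56, Elovl3 2.23, Bmp8b -4.46, Slc22a27 -3.20, Megf11 -3.14, Atp2b2 -2.72, Ddah1 -2.70, Phlda3 -2.09, Eda2r -1.85, Gbp3 -1.79 and p53 and senescence list median -0.51. By the interaction test, the difference of the diet effect between sexes at 40 weeks held 534 called genes, with log2 values of Cyp3a11 5.29, Myom2 4.68, Megf11 -4.43, Tcf24 -4.40, Slc22a26 -4.05, Wisp2 -3.74, Marco -3.59 and Dbp 3.95. By the interaction test, the difference of the diet effect between sexes at 60 weeks held 121 called genes, with log2 values of Cyp3a11 5.02, Mtnr1a 4.73, Gpnmb 4.35, Omd 4.0, Lrtm2 3.18, Scara5 -5.21, Cacna1h -4.50 and Sult4a1 -4.37. By the interaction test, the change of the diet effect from 20 to 60 weeks in males held 1312 called genes, with log2 values of Prtn3 10.31, Orm1 5.39, Cxcl14 5.10, Gpnmb -6.83, A4gnt -5.03, Mmp12 -4.96, Mogat1 -4.59, Gdf15 -3.37, Eda2r -2.66 and p53 and senescence list median -1.01. By the interaction test, the change of the diet effect from 20 to 60 weeks in females held 2650 called genes, with log2 values of Ckm 6.54, Myh2 6.35, H19 4.08, Osbpl3 3.62, Usp43 3.40, Cacna1h -4.80, Malrd1 -4.59, Col1a1 2.50, Mmp2 2.45 and Lyz2 1.89.

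In females at 40 weeks, clock genes differed between the diets in both directions. Across 16 clock genes, which are not independent replicates, the log2 fold changes followed the slopes on Dbp between animals within the 20 week groups (Pearson r 0.928, Spearman rho 0.918, permutation p 1e-05, the smallest the 100000 resamples can give). Another time of collection may therefore have contributed. A difference in library size would move all of them alike, against which 5 called clock genes went in the smaller direction. An effect of the diet on the clock gives the same pattern and stays open, with Dbp called higher in 2 of the 6 diet comparisons.

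In the same groups, acute phase genes were lower on the HF/HS diet. Single libraries do not account for it, since the list's median was -0.874 or lower whichever library was left out, nor does scaling, since the median was -1.06 with RLE size factors. Pancreas tissue is also argued against, since deviations of the acute phase and pancreas scores from the group means had a Pearson r of 0.0879 over 60 libraries (Spearman rho -0.00506, permutation p 0.501, r 0.0763 without the 2 farthest). An effect of the diet, or of handling of the controls, may underlie the value of -1.06 and stays open.

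Animal 91 of the males on the HF/HS diet for 60 weeks stood apart from its group. On a score of the 5162 genes called in males at 40 weeks, set to 0 at the mean of the controls and to 1 at the mean of the other 4 of its group, it was at 0.0298, within the range of -0.390 to 0.365 of the controls. Of 17 lists whose scores separated the controls from those 4, it lay within the controls in 10 and beyond them towards the HF/HS libraries in 5, among them glucose metabolism (7.55, controls 7.98 to 8.31, others 7.58 to 7.76), and beyond them the other way in 2, lipid droplet and fatty acid uptake (4.47, controls 4.68 to 5.56) and male-biased liver genes (8.01, controls 6.62 to 7.68). A swap with a control of that age is argued against, since 0 controls scored above 0.5, and so is library size, since its total of 15564238 counts lay within its group's range. A single wrong label and an animal that responded in part cannot be told apart, since the lists go both ways.

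Other splits of the same libraries, fitted alone, tested whether chance could give as many called genes. For each of the 6 diet comparisons 1 of 60 splits, the real one, gave as many. This argues against chance, at the smallest share that 60 splits can give. Males had 1889 genes against at most 9 at 20 weeks, 6773 against 2 at 40 weeks and 2203 against 876 at 60 weeks. Females had 1428 against 1, 5152 against 0 and 4507 against 7. With age on the control diet the share was also 1 of 60, with 2597 against 199 in males and 1845 against 45 in females. For sex it was 1 of 24, with 6268 against 2 on the control diet and 5192 against 0 on the HF/HS diet. For the difference between the sexes it was 1 of 40 at 40 weeks (2401 against 1) and at 60 weeks (68 against 1), and 1 of 40 for the change in females (1965 against 562). For the difference between the sexes at 20 weeks, 4 of 40 splits gave at least the real 28 genes (highest other 1251). For the change in males, 4 of 40 gave at least the real 325 (highest other 5201). In these splits sex or duration was shuffled within each diet. The 3 others as large in either comparison kept at least 4 more real labels in one diet than in the other. This brings sex or duration into the contrast, so they are no reference. The 32 and 33 others in which that difference was at most 2 gave at most 0 and 8 genes. These, picked after the result was seen, mix sexes or ages in a group, which can widen the spread, so chance stays open.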

How the results depend on the processing

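Leaving out the 4 libraries that stood apart and the clock covariate were chosen after the data had been seen, and the other alternatives before. The libraries left out were picked because they were unlike their groups, so their removal narrows the spread by construction. Fits of a comparison's own libraries called 1889 genes in place of 4096 in males at 20 weeks, 2203 in place of 3974 in males at 60 weeks and 1428 in place of 2872 in females at 20 weeks. For the control diet with age they called 2597 in place of 5212 in males and 1845 in place of 3853 in females, and for the change in males 325 in place of 1312. For the difference between the sexes they called 28 in place of 89 at 20 weeks, 2401 in place of 534 at 40 weeks and 68 in place of 121 at 60 weeks. Limma voom called 6134 genes in females at 40 weeks, and 41, 2918 and 395 for the difference between the sexes at 20, 40 and 60 weeks. DESeq2 called 176 and 205 for that difference at 20 and 60 weeks, and no filter 53 at 20 weeks. Without the libraries that stood apart it held 762, 1408 and 198 genes, and with the clock covariate 139 at 40 weeks. Apart from the construction named, the cause was not tested. All other counts of genes stayed within 1.5 times.

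Leaving out each library in turn gave 35 to 598 genes for the difference between the sexes at 20 weeks, 262 to 653 at 40 weeks and 78 to 151 at 60 weeks, and counts within 1.5 times for every other comparison. With the estimated correlation, camera called 0 lists in place of 20, 24 and 17 in males at 20, 40 and 60 weeks, and 0, 2 and 2 in place of 15, 17 and 21 in females. Unadjusted, it gave 10, 8, 7, 3, 7 and 8 lists, and fry called 19, 24, 16, 10, 20 and 22 after adjustment. For the difference between the sexes it called 1, 0 and 0 in place of 17, 20 and 14 (8, 3 and 4 unadjusted), where fry called 8, 8 and 0 (12, 16 and 5 unadjusted). For the change from 20 to 60 weeks it called 1 in place of 16 in males (fry 6) and 0 in place of 20 in females (5 unadjusted, fry 17).

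Of 2880 values of named genes under the alternatives, leave-one-out apart, 2732 kept their direction and their side of the threshold, 96 lost their call, 40 gained one and 12 turned direction. None of the 12 had passed the test, and the cause was not tested. They were Cyp4a12a in males at 20 weeks (-0.027 without the libraries that stood apart) and Sqle in males at 40 weeks (-0.01 with RLE size factors, -0.005 with DESeq2, -0.02 without a filter, -0.03 without small RNA genes, -0.018 without the libraries that stood apart). With voom they were Afp in males at 60 weeks (0.15), Afp in females at 40 weeks (-0.099) and Cyp4a14 in females at 60 weeks (0.008). Fasn in females at 40 weeks was at -0.016 without small RNA genes, and with the clock covariate Cdkn1a was at 0.21 and Gdf15 at 0.025. Leaving out a library gave ranges across 0 for Cyp4a12a in males at 20 weeks (-0.018 to 0.352). In males at 40 weeks this held for Afp (-0.07 to 0.152), Cdkn1a (-0.514 to 0.063) and Sqle (-0.134 to 0.431), and at 60 weeks for Afp (-0.194 to 0.3) and Gpc3 (-0.055 to 0.184). In females at 40 weeks it held for Fasn (-0.146 to 0.147), Afp (-0.023 to 0.281), Gpc3 (-0.314 to 0.09) and Gdf15 (-0.276 to 0.004), and at 60 weeks for Cyp4a14 (-0.407 to 0.517). RLE size factors and removal of small RNA genes moved the median log2 fold change of a comparison by at the farthest -0.0217 and -0.0418. The direction with more calls turned under at least 1 alternative in 13 of 15 comparisons. A depth of 10923963 to 20942463 counts limits genes near 0 counts, for which only bounds or ratios are given. No paired analysis was possible because no animal number occurs in more than 1 group.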

Other observations

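The tests of shared ageing and diet calls had been set before their results were seen. A hypothesis was that ageing on the control diet may share part of the diet response. Genes higher on the HF/HS diet at 40 weeks and higher at 60 than at 20 weeks on the control diet, comparisons with no library in common, numbered 748 in males against 552 expected of independent lists, a ratio of 1.36, between the limits set, which left it undecided. In females they numbered 262 against 293, a ratio of 0.893, which argued against it for these genes. Genes lower in both numbered 595 against 397 in males and 351 against 253 in females, ratios of 1.5 and 1.39, for which no limit had been set. Over all genes, the log2 fold changes of both comparisons had a Pearson r of 0.328 in males and 0.224 in females, which leaves a shared part open. Genes are not independent replicates, and ranges of animal number differed between the ages.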
